A study of Mus musculus with 6 samples.

How the data were processed

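RNA from whole eyes of C57BL/6J mice, a common inbred laboratory strain, was measured by RNA sequencing at 1.5 h and at 9.0 h after light onset. Per the labels, each library was made from pooled total RNA of 5 female mice aged 4 weeks, poly(A) RNA was isolated, and cDNA was made with random primers. There were 3 libraries at each time. The labels do not say whether the pools of a time held different mice, so p-values measure the spread between these libraries, which may be partly technical.

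The authors deposited 1 table per library with a value for each of 22692 gene symbols, in RPKM (reads scaled by gene model length and by the total reads of the library). The file headers name only the sample, and the unit was taken from the values. Values were not whole numbers and summed to between 393433 and 546836 per library. In genes with a single transcript length, low values multiplied by length fell on whole multiples of 1 step per library. Between 69.4% and 73.3% of them lay within 0.1 read of a whole number, against 8.1% to 11.3% at steps the data do not use. Per the submitters' processing notes, GSNAP and HTSeq were used with the mouse build mm9. Their versions, the gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here, nor is whether reads or fragments were counted. The labels give no batch or sequencing date.

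The step gave the total reads behind each library. Rounded to 10000 reads, these were 28990000, 12720000 and 13040000 at 1.5 h (replicates 1 to 3) and 31870000, 30160000 and 24090000 at 9.0 h. At 1 RPKM, a transcript of 2 kb then had between 25.4 and 63.7 reads. A library with 0 reads for such a transcript could hold up to 0.118 RPKM (3 reads, in the shallowest library), which covers counting error only.

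The comparison was 9.0 h minus 1.5 h. A count-based test had been planned, and because the values were RPKM the substitute written with it was used: limma 3.58.1 in R 4.3.3, with eBayes, trend and robust settings, on log2(RPKM + 0.1). Genes with at least 1 RPKM in 3 or more libraries were tested, which left 13490. Calls were made at a Benjamini-Hochberg adjusted p of 0.05, two-sided. Fold changes are on the log2(RPKM + 0.1) scale, which understates the change of low genes. No test on a single gene by permutation can go below p = 0.1 with 3 libraries against 3, so single genes were judged by the model across genes. On simulated values for the same 13490 genes, with 200 changed, 65% of 2-fold and 95% of 4-fold changes of this comparison were recovered, with 5 false calls. The simulation drew independent normal noise for each gene. It held no correlation between genes, no library trend with GC content and no read floor, so these rates may not carry over to the real libraries.

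Gene lists for clock genes, eye cell types and cell processes were written before the data were examined. Of 29 lists, 27 had at least 3 tested members and were tested with limma's camera, with a preset correlation of 0.01 between genes and adjustment over the 27. The blood list had 2 tested members, and the list for checking sex was not tested as a set. camera with an estimated correlation and fry were run beside it. Within lists, counts of members past the threshold are given over all tested genes and, for some lists, adjusted over the list alone. That second count is left out below for the lens, pigment epithelium, amacrine, adipose, synaptic and other clock lists, where it was 1 each.

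Genes named in the text were chosen by a rule also written before the data were examined. It took, among called genes with no overlap between the times and a mean of at least 2 RPKM, up to 12 with the largest fold in each direction. It added every measured member of the 2 main clock lists, up to 4 called members of each other list, and the 2 members with the highest mean where none was called. Not every gene the rule chose is shown. Genes named outside this rule are said to have been chosen after their values were seen.

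Gene length, GC content and near-identical copies came from GENCODE M21 transcripts of GRCm38, which is not the build of the files. It was used for sequence properties and names, and no coordinates are given. Of the tested genes, 13373 (99.1%) had a length, 1105 of all tested genes through an older symbol listed by RefSeq. Copies were found with minimap2 2.31 as another gene's transcript, at least 5000 nt away, with at least 95% identity. At first an alignment of at least 100 nt over at least 50% of the transcript was required, which gave 328 tested genes with a copy. After copy counts of several called genes had been seen, and genes such as Rpl21 had none, any alignment of at least 200 nt was also accepted, which gave 1018. The wider definition was therefore chosen with knowledge of called genes, and tests of copies are given under both. The alternative that leaves out genes with copies, and the copies marked for single genes and in the fold-change figure, use the wider one.

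Alternatives listed beforehand were other pseudocounts (0.01 and 1), other filters, lens and muscle genes left out with the values rescaled, the replicate number as a block, each library left out and stricter thresholds. Other scalings, removal of each library's trend with GC content and length (lowess, span 0.3), voom weights on estimated reads and the removal of genes with copies were chosen after seeing the data. Bootstrap intervals are 95% intervals from 10000 draws over genes, and permutation tests used 100000 draws. Genes are not independent replicates, so these describe the spread over genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.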

Results

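Whole-eye RNA was profiled early and late in the light phase, 1.5 h and then 9.0 h from its start, with 3 pooled libraries at each time. A whole eye holds retina, pigmented epithelium, lens, cornea, sclera and attached muscle, so each value is a mixture over these tissues. Depth was uneven: 1.5 h replicates 2 and 3 had 12720000 and 13040000 reads, and the other 4 libraries between 24090000 and 31870000. Log2 RPKM values of any 2 libraries correlated across genes with r between 0.948 and 0.989, so no library was a duplicate of another. The comparison asked which transcripts of the eye differ between morning and later day.

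Between 1.5 h and 9.0 h, Dbp, a clock-controlled transcription factor, rose from 26.92 ± 6.15 to 78.57 ± 4.73 RPKM (SD, n = 3 each; limma adjusted p = 0.0072). Egr1, an immediate-early transcription factor, rose from 6.49 ± 1.72 to 24.56 ± 3.54 RPKM (limma adjusted p = 0.00416). Npas2, a partner of the clock activator Arntl, fell from 2.62 ± 0.58 to 0.854 ± 0.031 RPKM (limma adjusted p = 0.0164). In all, 20 genes were higher and 10 lower at 9.0 h, of 13490 tested, and none of the 30 overlapped between the times. These 3 genes passed when any 1 of the 1.5 h libraries was left out, but without 9.0 h replicate 1 or 3 Dbp had limma adjusted p = 0.11 and 0.187 and Egr1 0.0847 and 0.102. Npas2 had 0.132, 0.0768 and 0.247 without 9.0 h replicate 1, 2 and 3.

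Among genes that rose were also Gm129 (Ciart, a clock repressor; log2 fold change 1.26 ± 0.17 SE) and Tcap, a protein of the muscle sarcomere (1.31 ± 0.19). Tsc22d3, a glucocorticoid-induced gene, rose by 0.90 ± 0.15. Limma adjusted p values of these 3 lay between 0.0152 and 0.045. Rpl21, Rps4x, Atp5g1 and Gabarapl2 passed with log2 fold changes of 2.76, 1.34, 1.80 and 1.40, but each has near-identical sequence elsewhere in the genome and its value is uncertain. The same holds for Gm11968 (4.86) and Gm16378 (3.32), at 0.142 and 0.412 RPKM at 1.5 h, whose calls ended at a pseudocount of 0.01 (6.35 and 3.71, limma adjusted p = 0.251 and 0.0712) and whose folds were 2.59 and 1.92 at a pseudocount of 1. Other settings ended them too, such as the replicate block for Gm11968 (limma adjusted p = 0.116) and leaving out 1.5 h replicate 3 for Gm16378 (0.0744). Gm129 has 1 near-identical copy. Snord42a (1.98) is a small nucleolar RNA gene of 65 nt inside another gene, so its reads can come from the host. Also higher were Fkbp11, Rps19, Marcksl1, Stmn1, Actg1, Rpl29 and Mif, listed after their values were seen. Of these, Rps19, Stmn1, Actg1, Rpl29 and Mif also have near-identical copies under the wider definition.

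Several of the largest falls were in retrocopied or very short genes. Aldoart2, a retrogene of the aldolase family, went from 8.09 ± 3.25 to 0.0351 ± 0.0608 RPKM, with 2 of the 3 libraries at 9.0 h listed at 0 (limma adjusted p = 0.000107). This depended on the pseudocount: its log2 fold change was −5.92 ± 0.36 SE, and at a pseudocount of 0.01 −8.40 ± 0.99, with limma adjusted p = 0.0515. Lrrc30 fell by 2.42 and 4930503E24Rik, an annotated pseudogene, by 2.26 on the log2 scale. Mirlet7d (−1.94) is a microRNA gene of 103 nt, and A330023F24Rik (−1.14) is annotated as a host of small RNAs. Hipk2, a nuclear kinase, fell from 13.52 ± 0.79 to 6.89 ± 1.05 RPKM, and Itgb8, the integrin beta 8 subunit, from 13.79 ± 1.40 to 7.05 ± 1.05 RPKM (limma adjusted p = 0.0357 and 0.0457). Under the wider definition of copies, Hipk2 shares near-identical sequence with 1 other gene. BC048507 and Mir145, a microRNA gene of 70 nt, also passed, and are named after their values were seen. Reads at a given RPKM scale with length. The calls of Snord42a, Mirlet7d and Mir145, at 1.914, 8.256 and 1.969 RPKM at 1.5 h, therefore rest on few reads. At a pseudocount of 0.01 BC048507 had limma adjusted p = 0.0744, and Gabarapl2, Tsc22d3, Itgb8 and A330023F24Rik had 0.0515 to 0.0555. Calls for single genes rested on few libraries: without 9.0 h replicate 1, 2 or 3, 4, 10 and 2 genes passed, without 1.5 h replicate 3, 13, and without 1.5 h replicates 1 and 2, 1245 and 61. The 1245 are not comparable with the others, since p-values in that fit were far smaller. At an unadjusted p of 0.05, 1491 genes passed, and 2454 genes (18.2%, against 10% by chance) did not overlap between the times.

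**Figure D1:**
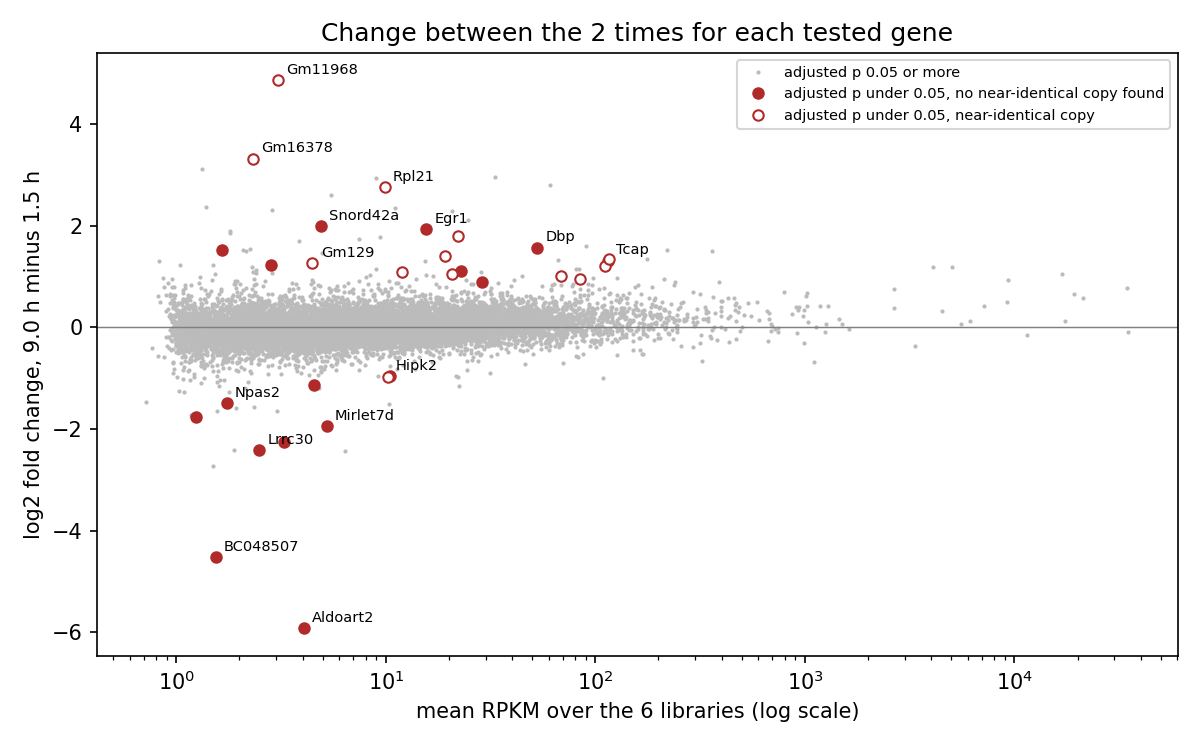
Log2 fold change (9.0 h minus 1.5 h) against mean RPKM over the 6 libraries (log axis) for the 13490 tested genes; red points passed an adjusted p of 0.05, and open red points have a near-identical copy under the wider definition. Of the 20 higher genes 12 have such a copy, against 1 of the 10 lower genes.

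Both main clock lists moved as groups. The list of clock genes that peak in the day had 12 measured members, all higher at 9.0 h, with a median log2 fold change of 0.50 (camera adjusted p = 1.96e-10; adjusted p = 0.168 with an estimated correlation). Of these, Dbp and Gm129 passed over all genes and 9 passed adjusted over the list alone. Nr1d1, a nuclear receptor that represses Arntl, had 62.57 ± 5.46 RPKM at 1.5 h and 105.8 ± 12.5 at 9.0 h. Its log2 fold change was 0.75, against 0.59 for Tef, 0.55 for Nr1d2, 0.50 for Per1 and 0.49 for Bhlhe40. Per2, Per3 and Cry2 had 0.47, 0.39 and 0.39, and Hlf and Bhlhe41 had 0.19 and 0.18. None of these 10 passed over all genes.

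The list of clock genes that are low in the day had 6 measured members, all lower at 9.0 h, with a median of −0.60 (camera adjusted p = 6.39e-06; adjusted p = 0.168 with an estimated correlation). Npas2 passed over all genes and 4 passed adjusted over the list alone. Arntl, the core activator, had 21.77 ± 4.58 RPKM at 1.5 h and 14.21 ± 0.55 at 9.0 h, and its partner Clock 13.21 ± 1.54 and 7.67 ± 0.46. The log2 fold changes were −0.59 and −0.77, with −0.21 for Nfil3 and −0.003 for Cry1. fry, which tests each list alone, gave adjusted p = 0.0233 and 0.0102 for the day-high and day-low lists, and passed no other list in direction. Its mixed test, which counts changes of either sign, also passed lists that camera did not. These were other clock (fry mixed adjusted p = 0.0105), glucocorticoid (0.00294), synaptic (0.00481), cholesterol (0.0347), immune (0.0378) and amacrine genes (0.0468). Phagocytosis and phosphoinositide genes had 0.4 and 0.253. Other clock genes, such as Csnk1d and Csnk1e (0.19 and 0.11), did not pass as a list of 10 (median −0.08, camera adjusted p = 0.696).

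**Figure D2:**
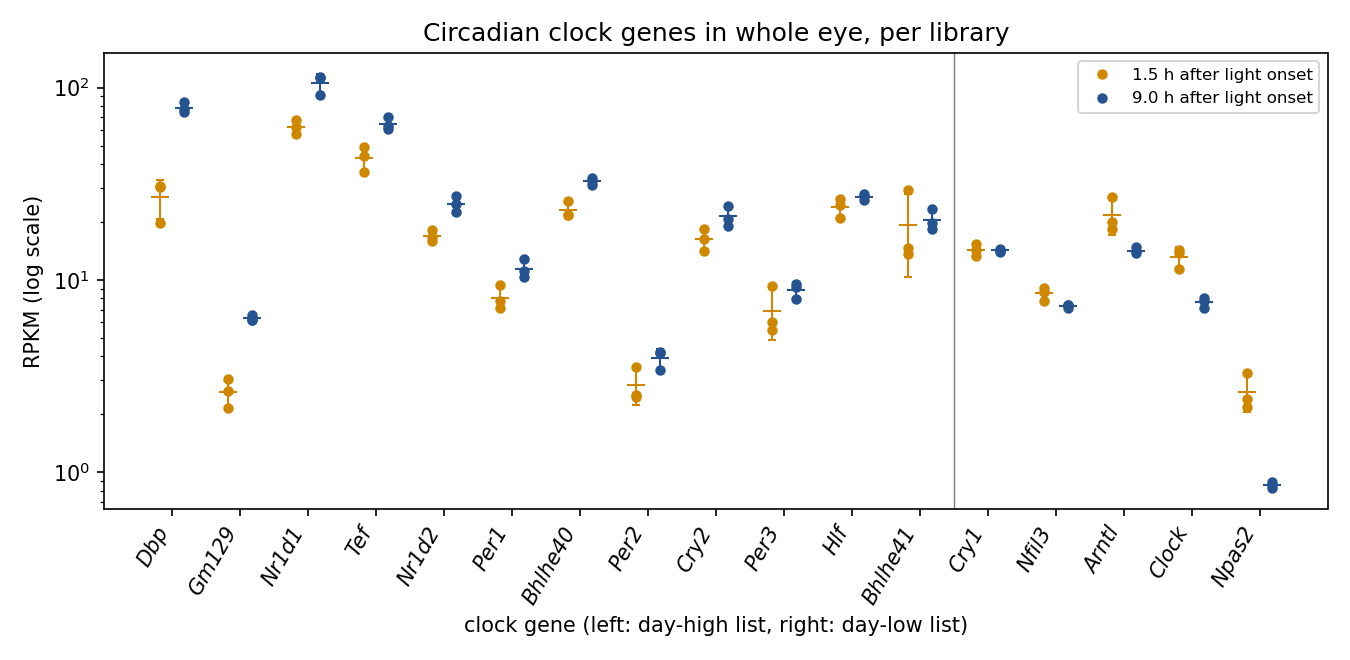
RPKM (log axis) of 17 clock genes per library; points are libraries, ticks means and bars SD over 3 libraries. Dbp lies between 19.82 and 30.68 RPKM at 1.5 h and between 74.5 and 83.75 at 9.0 h.

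Immediate-early genes, which are induced within minutes of cell stimulation, were higher as a list of 24 measured members (median 0.24, camera adjusted p = 1.92e-06; adjusted p = 0.413 with an estimated correlation). Egr1 passed over all genes and 8 members passed adjusted over the list alone. Fos had 10.3 and 20.82 RPKM at the 2 times (log2 fold change 1.04, limma adjusted p = 0.0622), a gene named after its value was seen. Tsc22d3 was the called member of the glucocorticoid list, whose 13 members had a median of −0.04 and a mean of 0 (camera adjusted p = 0.86). The heat shock list had a median of 0.22 over 18 members, with Hspb1 at 0.84 and Hsp90ab1 at 0.40, none called and 3 passing adjusted over the list alone. Its camera adjusted p was 0.0297, and 0.517 with an estimated correlation. Its median was 0.124 and 0.138 without 1.5 h replicate 1 and 9.0 h replicate 3, and −0.15 without genes that have a near-identical copy, and its camera adjusted p was 0.484 and 0.0687 without 1.5 h replicate 1 and 9.0 h replicate 2, and 0.204 after quantile normalization.

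Photoreceptor and pigment cell lists were lower at 9.0 h as groups, although no member passed over all genes. All 12 pigment genes, which serve melanin synthesis, had negative fold changes (median −0.32, camera adjusted p = 8.38e-05; adjusted p = 0.517 with an estimated correlation), such as Dct at −0.30 and Pmel at −0.10. The libraries overlapped between the times: their mean deviations were −0.104, 0.37 and 0.221 in 1.5 h replicates 1 to 3 and −0.134, −0.079 and −0.274 at 9.0 h, and without 1.5 h replicate 1 the median was −0.489. Rod genes had a median of −0.21, with 22 of 27 below 0 (camera adjusted p = 0.00156; adjusted p = 0.517 with an estimated correlation), and 2 passed adjusted over the list alone. Without 9.0 h replicate 2 the median was −0.131 (camera adjusted p = 0.0221). The rod transducin gene Gnat1 had −0.36. Bipolar cell genes had a median of −0.21 (camera adjusted p = 0.00481; adjusted p = 0.413 with an estimated correlation), with 1 of 12 passing adjusted over the list alone and Otx2 at −0.16. Genes of the retinal pigment epithelium had −0.22 (camera adjusted p = 0.0268; adjusted p = 0.554 with an estimated correlation), with its most abundant members Ttr and Trf at 0.12 and 0.10. Cone genes had −0.18 (camera adjusted p = 0.0485; adjusted p = 0.517 with an estimated correlation), with Gnb3 at −0.02 and Opn1sw at −0.29. The medians of the pigment epithelium and cone lists were −0.361 and −0.287 without 1.5 h replicate 1, and −0.072 and −0.105 without 1.5 h replicate 2. The pigment epithelium list had camera adjusted p = 0.213, 0.0732 and 0.189 without 1.5 h replicate 2, 1.5 h replicate 3 and 9.0 h replicate 1. The cone list passed without 9.0 h replicate 3 (0.0369), and had 0.0535 to 0.13 without any other library, 0.061 with no filter, 0.0602 with the replicate block and 0.0524 with voom weights.

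Lens, connective tissue and muscle lists were higher at 9.0 h, and this depended on 1.5 h replicate 1. Lens genes, mostly crystallins, had a median of 0.41 over 25 members, with Cryaa at 0.78 and Crybb2 at −0.09. Corneal stroma and sclera genes had 0.46 over 19, of which 6, all collagens, passed adjusted over the list alone, while the most abundant members Ptgds and Dcn had −0.69 and −0.07. Skeletal muscle genes had 0.37 over 25, with Tcap called and 3 passing adjusted over the list alone. The camera adjusted p values were 1.06e-05, 0.000136 and 0.00168, and 0.517, 0.517 and 0.596 with an estimated correlation. In 1.5 h replicate 1 these lists lay 0.71, 0.73 and 0.67 below their mean over the libraries on the log2 scale, and lens genes took 20.4% of estimated reads there, against 26.3% to 33.7% in the other 5 libraries. Without that library the medians were 0.257, 0.153 and 0.145 and the adjusted p values 0.0813, 0.375 and 0.899 (stroma and sclera had a median of 0.29 without 9.0 h replicate 1). The lens rise also depended on the scaling: after quantile normalization its median was 0.067 (camera adjusted p = 0.204).

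Corneal epithelium genes had a median of 0.23 over 17 members (camera adjusted p = 0.0323; adjusted p = 0.554 with an estimated correlation), with Krt12 at −0.04 and Aldh3a1 at 0.06. Lysosome and autophagy genes had 0.12 over 33 members (camera adjusted p = 0.0268; adjusted p = 0.517 with an estimated correlation), and Gabarapl2 was the called member. The median of the corneal list was 0.402 and 0.039 without 1.5 h replicates 1 and 3, and that of the lysosome list 0.059 without 1.5 h replicate 1. The corneal list had camera adjusted p = 0.32 and 0.306 without 1.5 h replicate 3 and 9.0 h replicate 3, and the lysosome list 0.338 and 0.0509 without 1.5 h replicate 1 and 9.0 h replicate 1. After quantile normalization both lists had camera adjusted p = 0.378, with medians of 0.155 for the corneal and 0.04 for the lysosome list. The lysosome list had camera adjusted p = 0.0848 with GC and length trends removed.

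**Figure D3:**
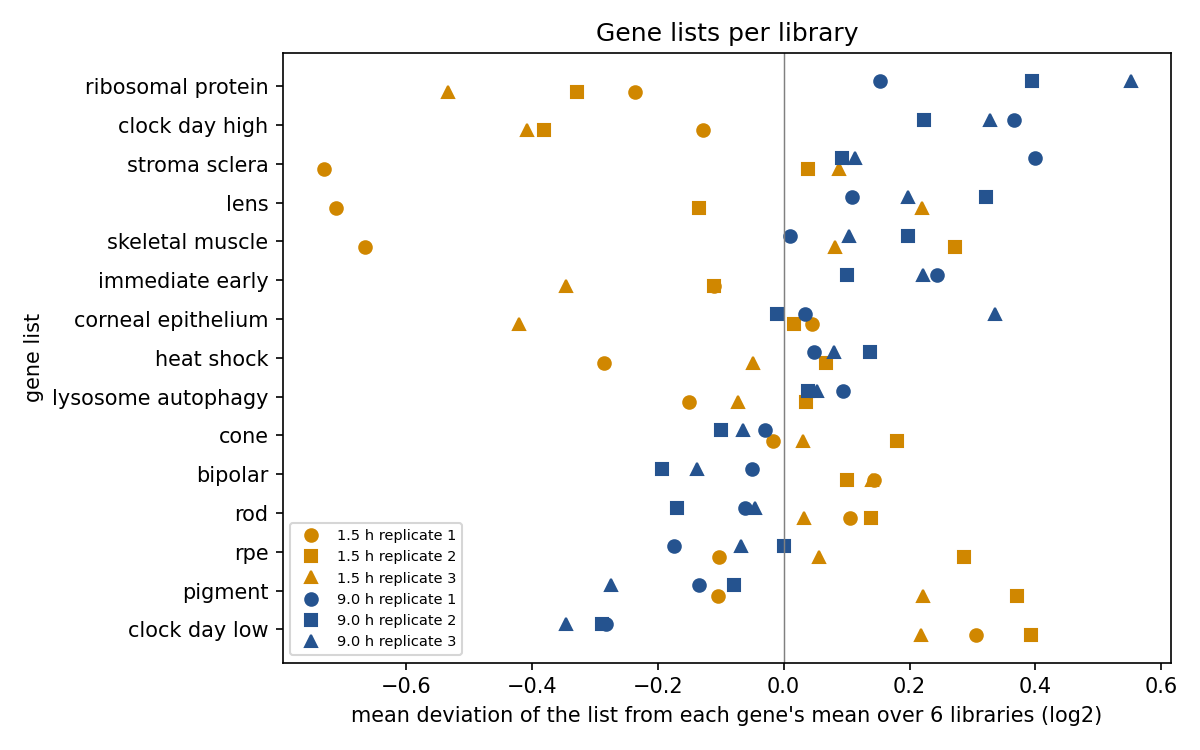
Mean deviation of each list from each gene's mean over the 6 libraries (log2), per library, for the 14 lists past camera and for ribosomal protein genes, a list chosen after seeing the data. Values of the 2 times do not overlap for the clock, immediate-early, rod, cone, bipolar, lysosome, stroma and sclera, and ribosomal protein lists, while 1.5 h replicate 1 stands apart at −0.73 for stroma and sclera, −0.71 for lens and −0.67 for skeletal muscle.

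Genes of phagocytosis, by which pigment epithelium takes up shed photoreceptor outer segments, did not pass. Of 25 measured members none was called, the median was −0.02 (camera adjusted p = 0.767), and Anxa2 and Tulp1 had 0.32 and 0.13. Phosphoinositide signalling genes did not pass either: of 78 measured members none was called, the median was −0.10 (camera adjusted p = 0.0642), and Pitpnm1 and Inpp5k had 0.11 and −0.01. The phosphoinositide list passed when 1.5 h replicate 2 or 9.0 h replicate 1 was left out (0.00344 and 0.00529). Its median was −0.15 without 9.0 h replicate 1, −0.046 without 1.5 h replicate 1 and −0.039 without 9.0 h replicate 3.

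Other retinal lists had medians near 0: amacrine 0.07, with Calb2 at 0.19, ganglion cell −0.02, with Nefl and Thy1 at −0.28 and 0.20, and Mueller glia −0.02, with Apoe and Clu at 0.01 and 0.03. Their camera adjusted p values were 0.174, 0.526 and 0.526. Without 1.5 h replicate 1 the Mueller list had a median of −0.203 (camera adjusted p = 0.07), and −0.214 with GC also removed (0.0164). Synaptic genes (median −0.08, Slc17a7 0.33, Snap25 −0.31), immune genes (0.16, Lyz2 −0.45, Cd74 0.22) and adipose genes (−0.49, Fabp4 −0.06, Lpl −0.69) gave 0.135, 0.0944 and 0.0529. These lists passed in some settings: synaptic without 1.5 h replicate 2 (0.0412), after quantile normalization (0.00373) and with GC removed (0.0307), immune without 9.0 h replicate 2 (0.0321) and without genes that have copies (0.016), and adipose without 1.5 h replicate 1 or 9.0 h replicate 2 (0.00169 and 0.0221), at a pseudocount of 1 (0.046), with the replicate block (0.0392) and with GC removed (0.0464). The immune median was 0.064 without 1.5 h replicate 3, and the adipose median −0.804, −0.273 and −0.306 without 1.5 h replicates 1, 2 and 3. Genes of smooth muscle and vessels (−0.09, Acta2 −0.24, Tagln −0.18), cholesterol synthesis (−0.12, Fdps 0.61) and retinal rhythm outputs (0.02, −0.02 with lens genes left out; Cirbp 0.39, Drd4 0.26) gave 0.696, 0.232 and 0.328. The smooth muscle and vessel list had a median of −0.184 without 1.5 h replicate 1 (0.322), and passed there with GC also removed (−0.184, 0.0337). The 2 tested blood genes, Beta-s and Alas2, had 0.10 and −0.07 and were not tested as a list. These values rest on 1.5 h replicate 3, with 366.9 RPKM for Beta-s and 7.821 for Alas2, against 41.87 and 53.03, and 1.827 and 1.546, in the other 1.5 h libraries. At 9.0 h they had 82.68 to 117.7 and 2.476 to 2.852 RPKM, and without 1.5 h replicate 3 the log2 fold changes were 1.08 and 0.65 (limma adjusted p = 0.133 and 0.346).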

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

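The Y-linked genes were looked at as a check of the labels, which give female mice. In 1.5 h replicate 3, Ddx3y had 0.479, Uty 0.205, Kdm5d 0.126 and Eif2s3y 0.78 RPKM, about 19, 7, 6 and 8 reads, and all 4 were listed at 0 in the other 5 libraries. These values stand out because they are above the level that 3 reads would give in a pool labelled female, and no explanation was tested. The same library had the highest values of both tested blood genes. Xist, which is expressed from the inactive X chromosome of females, had 39.26, 27.6 and 19.74 RPKM in 1.5 h replicates 1 to 3 and 13.35, 15.49 and 14.06 at 9.0 h (limma adjusted p = 0.125).

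The 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split called 30 genes and the highest of the others 2, and in 1 of the 10 splits, the real one, as many genes passed. For lists the real split gave 14 and the highest other 9, again with 1 split reaching the real value.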

How the results depend on the processing

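The medians of the day-high and day-low clock lists stayed between 0.44 and 0.61 and between −0.65 and −0.50 in every setting tried. With the preset correlation, these lists and those of immediate-early, rod, pigment and bipolar genes passed camera in each of them. Counts of genes were not stable. Against 20 higher and 10 lower genes, the numbers were 16 and 6 at a pseudocount of 0.01 (22 of the 30 kept), 19 and 10 with no filter on low values (19 kept), 5 and 3 at an adjusted p of 0.01, and 87 and 54 with the replicate number as a block (27 kept). Deviations of same-numbered libraries from the means of their times correlated at 0.35, 0.48 and −0.21, and not every library correlated best with its own number, so the numbers were not taken to pair the samples. Leaving out 1 library gave between 0 and 669 higher and between 2 and 576 lower genes, and between 9 and 14 lists. The most genes came without 1.5 h replicate 1, where all 30 were kept and 9 lists passed, and the fewest genes without 9.0 h replicate 3, where 2 were kept. Without 1.5 h replicate 1, Npas2 had a log2 fold change of −1.325 ± 0.228 SE, against −1.49 ± 0.199 in the main fit. Its limma adjusted p nevertheless went from 0.0164 to 1.01e-06, and that of Aldoart2 was 3.78e-114. The 1245 calls of that fit are therefore not comparable with the other counts, and keeping all 30 there is weak support. The following were chosen after seeing the data. Median-ratio scaling gave 9 and 6 and quantile normalization 10 and 5 (15 kept in each), GC and length trends removed 33 and 20 (25 kept), GC removed with the replicate block 57 and 28 (25 kept), and GC removed without 1.5 h replicate 1 199 and 125 (29 kept). Leaving out genes with near-identical copies (wider definition) gave 7 and 7 (14 kept of 17 tested). GC removed gave 28 and 15 (22 kept), and voom weights 19 and 10 (26 kept). Of the 14 lists, 0 passed with an estimated correlation and 2 with fry in direction. No named or called gene passed with the opposite sign in any setting. Except where fewer genes or libraries were tested, the cause was not tested. The planned median-of-ratios and upper-quartile factors, the Wald count test and the CPM filter were not run, since they need counts. Depth limits low genes most in 1.5 h replicates 2 and 3, where 3 reads correspond to 0.118 and 0.115 RPKM for a 2 kb transcript.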

Other observations

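All tests in this part were chosen after the results they bear on had been seen. For the fall without 1.5 h replicate 1, the bound of 0 replaced a stricter one that the interval narrowly missed. Ribosomal protein genes, a list not among those written beforehand, had a median log2 fold change of 0.58 over 67 measured members, of which 58 lay above 0 and 4 (Rpl21, Rps4x, Rps19 and Rpl29) were called. camera gave p = 2.43e-25 with the preset correlation and p = 0.0276 with an estimated one. The median stayed between 0.49 and 0.70 when each library was left out in turn, and was 0.62 without 1.5 h replicate 1.

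Called genes often had near-identical copies. With the wider definition 13 of the 30 had one, against 7.5% of other tested genes (odds ratio 9.38, 95% interval 4.18 to 20.58, Fisher's exact test p = 9.42e-08), and with the first definition 7 of 30 against 2.4% (12.34, 4.44 to 29.97, p = 6.27e-06). Annotated pseudogenes and retrogenes made up 5 of the 30 and 54 of 13343 others (odds ratio 49.07, 14.15 to 137.7, Fisher's exact test p = 1.84e-07), 2 higher and 3 lower at 9.0 h, so reads placed differently between genes and their retrocopies at the 2 times may account for these calls. Whether copies account for most of the calls stays open. Of called genes, 56.7% had none under the wider definition and 76.7% under the first. With annotated pseudogenes and retrogenes set aside too, the shares were 46.7% (14 genes) and 66.7% (20). Of the 5 annotated genes, no copy was found for Aldoart2, BC048507 and 4930503E24Rik, while Gm11968 and Gm16378 had 5 and 8 under the wider definition. Whether read length or alignment differed between the times is not given in the sources used here, and a change in the transcripts themselves stays open.

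For the ribosomal protein genes, the answer on copies depended on the definition. The 5 without a copy under the wider one had a median of 0.38 (−0.66 to 0.67), too few to decide, and the 28 under the first had 0.51 (0.29 to 0.66), which alone would argue against copies, although 23 of those share a 200 nt stretch with another gene. The fold change and the number of copies had Spearman rho 0.21 across genes (permutation p = 0.086) under the wider and 0.13 (p = 0.27) under the first. Trends with GC content and length are argued against as the whole cause, since the median was 0.55 (0.45 to 0.67) after their removal. Some ribosomal protein genes with copies, named after their values were seen, also differed widely within 1.5 h. In replicates 1 to 3 Rps28 had 61.7, 9.596 and 4.218 RPKM and Rpsa 19.43, 6.323 and 2.141. Rpl13 went the other way, with 8.364, 52.84 and 36.64. Time of day does not account for a spread within 1 time, and its cause was not tested. Replicates 2 and 3, which differed from replicate 1 in these genes, were the shallowest libraries, with 12720000 and 13040000 reads against 28990000. Both are from 1.5 h, so depth is partly confounded with time. Not every such gene split this way: Rps7 had 6.27, 2.286 and 22.32 RPKM in 1.5 h replicates 1 to 3. Shared reads and a change with time of day cannot be told apart here, because most of these genes have copies.

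Rod, pigment and bipolar genes were lower and lens and connective tissue genes higher at 9.0 h, a difference in median of 0.66. Across genes, the log2 fold change rose with GC content (Spearman rho 0.33). In single libraries the correlation with GC content ran from −0.60 in 1.5 h replicate 2 to 0.49 in 9.0 h replicate 3. GC content is argued against as the whole cause of the difference, since 0.54 (0.44 to 0.72) was left after its removal. A smaller share of retina in the 9.0 h pools would lower all retinal genes alike; bipolar and rod genes had −0.209 and −0.212 (difference not tested), while amacrine, ganglion cell and Mueller genes, compared after their medians had been seen, differed from rod genes by 0.21 (permutation p = 0.00039), but by 0.07 (p = 0.46) without 1.5 h replicate 1, where Mueller genes had −0.203, so this stays open. Without that library a fall remained, since rod, pigment and bipolar genes had a joint median of −0.23 (−0.34 to −0.12), against −0.24 with it. Rod and bipolar genes fell less (−0.145 and −0.156) and pigment genes more (−0.489, against −0.318). Pigment genes lay at −0.104 in that library, against 0.37 and 0.221 in 1.5 h replicates 2 and 3, so leaving it out had to deepen their fall. The interval is over genes that share libraries and does not measure the spread between libraries, so it cannot decide how much of the fall that library carries. It could carry the rise, whose median was 0.21 (−0.09 to 0.35) without it, against 0.42, and the difference was 0.45 (0.13 to 0.66). Dissection of the pools and a change with time of day cannot be told apart with these libraries.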
